A study of Vitis with 24 samples.

How the data were processed

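Gene expression was measured by RNA sequencing in buds of grapevine (Vitis), taken at nodes 3 to 12 of the shoot. The vines were 2 siblings of an F2 population, named F2 040 and F2 110. Per the labels' protocols, single-end libraries were made with a stranded kit from total RNA. Spur-pruned vines had grown under long days until the shoots held 12 to 15 nodes, and were then kept under long days (LD, 15 h of light) or moved to short days (SD, 13 h) for 28 or 42 days. The series design gives 3 replicates per treatment with 10 vines in each, so p-values measure the spread between such pools. The 8 groups of 3 libraries follow the labels for genotype, photoperiod and day, and all 24 libraries were used.

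The deposited count table holds whole-number counts for 29970 gene identifiers in 24 columns, and the deposited FPKM table holds FPKM (fragments scaled to gene length and library size) for the same identifiers; its 3 empty last columns were not used. Per the submitters' processing notes, bcl2fastq, FastQC, cutadapt, TopHat, Cufflinks and edgeR were used by the authors, with no versions, roles or order stated. The genome build, the annotation and the program that counted the reads are not given in the sources used here, nor is whether strand was used in counting. Counts of near-identical or overlapping genes are therefore uncertain. No reference came with the series and the tables pair no identifier with a name, so genes are given by identifier only, without position or function. For the same reason 28 gene lists fixed by product name, 2 of which also held 15 locus identifiers written from memory, had 0 members that could be assigned, and none was tested.

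The counts were analysed as deposited. Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3, which kept 21081 genes; 3976 genes had no count in any library. Library sizes were scaled by TMM, and 1 quasi-likelihood model with 8 group means was fitted over all 24 libraries with glmQLFit and tested with glmQLFTest. The common biological coefficient of variation was 21.8%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 21081 genes of a contrast, and "rose", "fell", "higher" or "lower" is written of genes called in this way. The 14 contrasts were SD against LD in each genotype on each day (4), the difference of that effect between genotypes (2) and between days (2), F2 110 against F2 040 under LD (2), and day 42 against day 28 in each genotype and photoperiod (4). Log2 fold changes carry the standard error implied by the quasi-likelihood F statistic. Levels are given as CPM, the usual scaling of counts to the library total, as mean ± SD of 3 libraries. The median log2 fold change over all tested genes ranged from -0.02 to 0.01 in the 14 contrasts.

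The genes named were chosen by a rule set before the data were examined: in each contrast, the 2 called genes with the largest rise and the 2 with the largest fall among those with a mean CPM of at least 1, and in SD against LD only where all 3 libraries of one group lay beyond all 3 of the other, which chance alone gives in 10% of unchanged genes. The rule had allowed more genes where names were available. Where the lower group held 0 counts, the fold is a lower bound against a floor of 3 counts over that group; with 1 to 3 counts it is the ratio of counted shares with a 95% exact binomial interval. Both cover counting error only. Expected overlaps of calls are n1 × n2 / N per direction for independent lists.

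Total counts ranged from 10444810 to 20041164 per library. Counts were simulated with means, depths and dispersions taken from the real data, and 20805 genes were kept. The test of SD against LD in F2 040 on day 28 recovered 57.6% of 99 genes changed 2-fold. It recovered 89% of 100 changed 4-fold and called 2 unchanged genes. The test of the difference of effects between genotypes on day 28 recovered 28.3% and 72%, with 4 unchanged genes called. The simulation was not shown to hold unequal spread between groups or a library that lies apart. Its few calls of unchanged genes thus do not show that false calls are rare in the real data. Within every group, each pair of replicates differed by more than sampling noise, with a variance of 5.34 to 85.8 times that of counting alone.

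The labels number the replicates 1, 2 and 3 in every group. Residuals from the group means were correlated between libraries of the same number, and the numbers were taken to pair the samples where all 3 correlations passed 0.1. That was so in 3 contrasts. In SD against LD in F2 110 the correlations were 0.35, 0.21 and 0.39 on day 28 and 0.21, 0.22 and 0.41 on day 42, and in day 42 against day 28 under LD in F2 040 they were 0.28, 0.34 and 0.47. In the differences of effects some pairs of groups passed and others did not, and these contrasts were not taken as paired. On day 28, F2 110 LD with F2 040 SD reached 0.53, 0.48 and 0.31, and F2 110 SD with F2 040 LD 0.29, 0.16 and 0.28. The labels do not say that a number marks a shared batch.

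The alternatives fixed before the data were examined were edgeR with median-of-ratios size factors, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in every library of a group, the replicate number as a block, a fit of only the libraries compared, limma 3.58.1 with trend on log2(FPKM + 0.1) and log2(FPKM + 1) of 20542 genes at an FPKM of at least 1 in 3 libraries, and each library left out in turn. The block within only the libraries compared was added after seeing the data. Other splits of the libraries were refitted, 10 per comparison of 2 groups and 25 drawn per difference of effects.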

Results

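RNA from buds of 2 sibling grapevines was compared between long days (LD, 15 h of light) and short days (SD, 13 h) after 28 and 42 days. The siblings, F2 040 and F2 110, belong to an F2 population, and the series addresses dormancy induction by photoperiod. Each of the 8 combinations of genotype, photoperiod and day was measured in 3 libraries. The total count per library was 15601235 to 16246289 in F2 040 LD 28 d, 13652491 to 14638687 in F2 040 SD 28 d, 17077539 to 17681317 in F2 040 LD 42 d and 10528673 to 15438811 in F2 040 SD 42 d. In F2 110 it was 13291880 to 20041164 in LD 28 d, 10444810 to 19980873 in SD 28 d, 10667102 to 15003282 in LD 42 d and 14068655 to 17691800 in SD 42 d. The 10 genes with the most counts took a mean of 3.62% to 5.38% of a group's counts.

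On principal components of log2 CPM, the first component held 41.5% of the variance and the second 17.4%. All F2 040 groups had negative means on the first component and all F2 110 groups positive ones. Among F2 040 groups, SD 42 d stood apart, with a second-component score of 63.5 ± 11.4 (SD, n = 3), whereas LD 28 d, SD 28 d and LD 42 d were at -8.28 ± 6.87, -5.68 ± 3.12 and -1.85 ± 18.6. In F2 110 the second component was -59.9 ± 1.52 in LD 28 d, -19.2 ± 7.04 in SD 28 d, -8.54 ± 35.0 in LD 42 d and 39.9 ± 20.9 in SD 42 d.

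**Figure D1:**
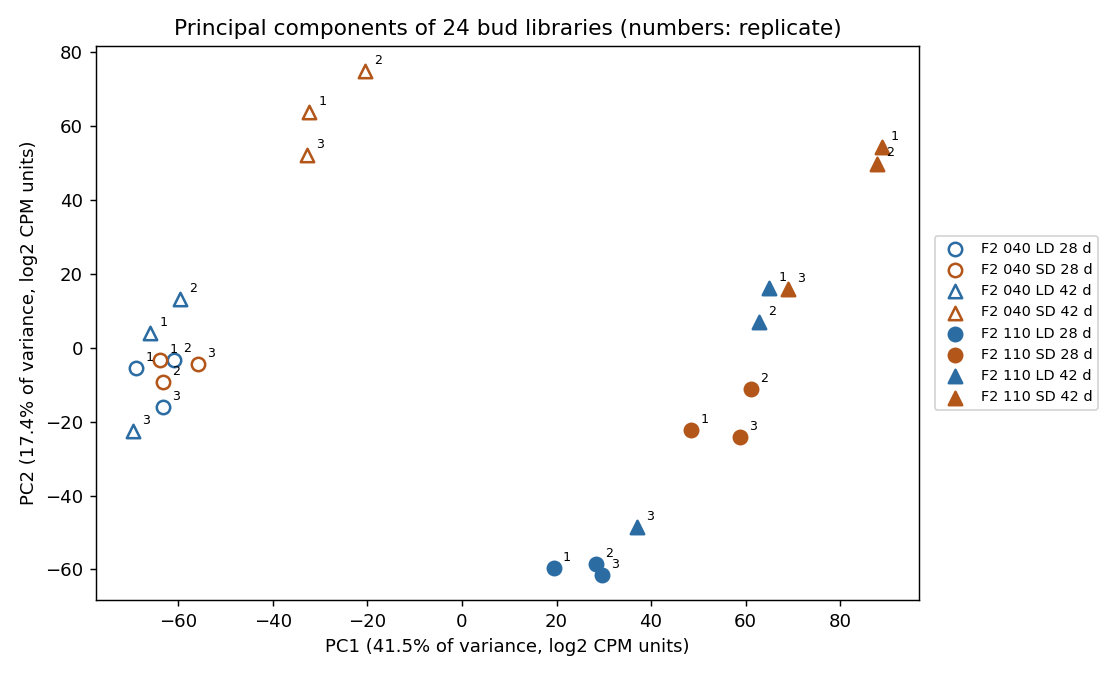
Scores of the 24 libraries on the first 2 principal components of log2 CPM (41.5% and 17.4% of the variance, each point 1 library). The genotypes part on the first component, and the F2 040 SD 42 d libraries lie away from the other F2 040 libraries on the second.

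The first comparison asked which bud genes differed between SD and LD in F2 040 after 28 days. VIT_05s0049g00790 rose from 1 count over the 3 LD libraries, in replicate 1, to 2.64 ± 2.11 CPM (SD, n = 3) in SD, a ratio of 127.9 with a counting interval of 22.5 to 5097. Without that replicate the fitted log2 fold change went from 6.41 to 8.25. VIT_12s0028g02800 rose from 0.123 ± 0.123 to 9.15 ± 15.2 CPM, with 1 SD library at 26.7 CPM. VIT_15s0048g01200 fell from 3.64 ± 5.45 to 0.168 ± 0.185 CPM and VIT_00s0187g00090 from 2.83 ± 1.501 to 0.161 ± 0.219 CPM, log2 fold changes of -4.48 ± 1.398 and -4.15 ± 0.91 (SE). Of 2155 genes called, 1488 were higher and 667 lower in SD; 744 of the higher and 120 of the lower ones changed at least 2-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, p was 0.0121 for each of the risen genes, 0.0472 for VIT_15s0048g01200 and 0.00715 for VIT_00s0187g00090. A fit of only these 6 libraries called 1118 genes. The count was 1124 without LD replicate 2, 1289 without LD replicate 3 and 966 without SD replicate 2, and with 1 library left out only VIT_00s0187g00090 of the 4 genes passed in every case. VIT_05s0049g00790 reached an edgeR Benjamini-Hochberg adjusted p of 0.0569 without LD replicate 2 and 0.051 without LD replicate 3, and VIT_12s0028g02800 0.0601 without LD replicate 2 and 0.508 without SD replicate 3. VIT_15s0048g01200 reached 0.553 without LD replicate 2 and 0.138, 0.16 and 0.078 without SD replicates 1, 2 and 3 by the same edgeR test with Benjamini-Hochberg adjustment. The log2 fold change of VIT_12s0028g02800 was 1.33 without SD replicate 3 and 6.94 without LD replicate 3. That of VIT_15s0048g01200 was -1.65 without LD replicate 2 and -5.62 without SD replicate 3, and that of VIT_00s0187g00090 was -6.07 without SD replicate 2. VIT_12s0028g02800 did not pass limma on log2(FPKM + 0.1) or log2(FPKM + 1), with Benjamini-Hochberg adjusted p of 0.0912 and 0.149, and edgeR with no low-count filter gave VIT_15s0048g01200 0.0527. A replicate block within only these 6 libraries, a fit chosen after seeing the data, called 0 genes, with 4884 at an unadjusted p under 0.05. It gave VIT_00s0187g00090 an edgeR Benjamini-Hochberg adjusted p of 0.0504, though the numbers did not pair the libraries here.

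After 42 days in F2 040, VIT_05s0049g00550 was at 0.514 ± 0.388 CPM in LD and 25.2 ± 16.8 CPM in SD (SD, n = 3), a log2 fold change of 5.55 ± 0.93 (SE), and VIT_19s0015g00540 rose from 0.172 ± 0.115 to 3.34 ± 0.411 CPM, a log2 fold change of 4.20 ± 0.73. VIT_03s0110g00370 and VIT_11s0103g00050, at 2.72 ± 2.08 and 2.68 ± 1.73 CPM in LD, had no count in SD and were at least 36.6-fold and 36.05-fold lower against a floor of 3 counts over the group. Of 3412 genes called, 1781 were higher and 1631 lower in SD. The lower genes changed more, with 855 at least 2-fold lower beside 255 at least 2-fold higher. Adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.00256 and 0.00285 for the risen genes and 0.037 and 0.0301 for the fallen ones. A fit of only these 6 libraries called 1712 genes, with an edgeR Benjamini-Hochberg adjusted p of 0.0508 for VIT_11s0103g00050. The log2 fold change of VIT_05s0049g00550 was 6.44 without LD replicate 3 and 4.86 without SD replicate 2. The count was 1763 without LD replicate 1, 1100 without LD replicate 3, and 1484, 1098 and 2216 without SD replicates 1, 2 and 3. By the same edgeR test, Benjamini-Hochberg adjusted p of VIT_03s0110g00370 was 0.0696 and 0.111 without LD replicates 1 and 3 and 0.102, 0.0993 and 0.0821 without SD replicates 1, 2 and 3, and that of VIT_11s0103g00050 was 0.0618, 0.0851, 0.0874, 0.086 and 0.0699 in the same order.

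In F2 110 after 28 days, VIT_05s0049g00550 was again among the risen genes, from 2.07 ± 0.815 CPM in LD to 148 ± 37.5 CPM in SD (SD, n = 3), a log2 fold change of 6.20 ± 0.86 (SE). VIT_19s0085g00920 rose from 0.125 ± 0.115 to 5.80 ± 0.756 CPM (log2 fold change 5.46 ± 1.11). VIT_07s0031g01120 fell from 2.48 ± 1.72 to 0.0849 ± 0.0227 CPM (-4.73 ± 0.78) and VIT_00s0250g00090 from 4.63 ± 3.12 to 0.290 ± 0.183 CPM (-3.85 ± 0.82). In all, 881 genes were called, 431 higher and 450 lower in SD, with 161 and 242 of them changed at least 2-fold. By edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p was 0.00149, 0.0135, 0.00413 and 0.0161 in the order named. Replicates of the same number varied together here. With the replicate number as a block over all 24 libraries, which is not a pairing of these 6 alone, 1492 genes were called; DESeq2 called 1646. The block within only these 6 libraries, a fit chosen after seeing the data, called 1076 genes and gave VIT_00s0250g00090 an edgeR Benjamini-Hochberg adjusted p of 0.0563, and limma on log2(FPKM + 1) gave VIT_19s0085g00920 0.0595. The count was 133 and 335 without LD replicates 1 and 2, and 69 and 118 without SD replicates 2 and 3. In those cases edgeR's Benjamini-Hochberg adjusted p of VIT_00s0250g00090 was 0.0565, 0.055, 0.107 and 0.0623, and that of VIT_19s0085g00920 was 0.0648, 0.0517 and 0.0567 without LD replicates 1 and 2 and SD replicate 2. The log2 fold change of VIT_07s0031g01120 was -4.08 without LD replicate 3 and that of VIT_00s0250g00090 -4.61 without SD replicate 3.

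After 42 days in F2 110, VIT_00s0194g00380 rose from 0.523 ± 0.454 CPM in LD to 10.9 ± 0.787 CPM in SD (SD, n = 3; log2 fold change 4.44 ± 0.57, SE). VIT_05s0049g00550 rose from 58.3 ± 58.7 to 1045 ± 265 CPM (4.17 ± 0.74). VIT_02s0154g00290, at 2.80 ± 3.68 CPM in LD, had no count in SD and was at least 37.95-fold lower, with 75 of its 95 counts in LD replicate 2. The bound was 10.9-fold without that library and 57.3-fold without LD replicate 3. In F2 040 this gene rose on day 28, from 1.95 ± 1.49 to 29.5 ± 0.581 CPM (log2 fold change 3.82 ± 0.80). It fell there on day 42, from 30.3 ± 6.95 to 0.917 ± 1.14 CPM (-4.99 ± 0.89). There edgeR's Benjamini-Hochberg adjusted p was 0.00662 and 0.00378. VIT_07s0005g03060 fell from 52.8 ± 54.0 to 3.01 ± 1.94 CPM (-4.05 ± 0.58). Of 2941 genes called, 1241 were higher and 1700 lower in SD, and 179 and 737 of these changed at least 2-fold. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.000383, 0.00165, 0.0173 and 0.000382 in the order named. Replicates of the same number varied together, and with a block within only these 6 libraries, a fit chosen after seeing the data, 1576 genes were called; without the block these 6 libraries gave 549. In that last fit edgeR's Benjamini-Hochberg adjusted p was 0.0738 for VIT_05s0049g00550 and 0.0569 for VIT_07s0005g03060. The count was 1041 without LD replicate 3, 1269 without SD replicate 1 and 1126 without SD replicate 2. For VIT_02s0154g00290 edgeR's Benjamini-Hochberg adjusted p was 0.0844 without LD replicate 2 and 0.0597 and 0.0579 without SD replicates 1 and 2, and limma on log2(FPKM + 1) gave 0.0621. The log2 fold change of VIT_00s0194g00380 was 5.07 and 3.79 without LD replicates 1 and 3, and that of VIT_05s0049g00550 was 5.34 without LD replicate 1. That of VIT_07s0005g03060 was -2.81 without LD replicate 3 and -4.72 without SD replicate 3.

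**Figure D2:**
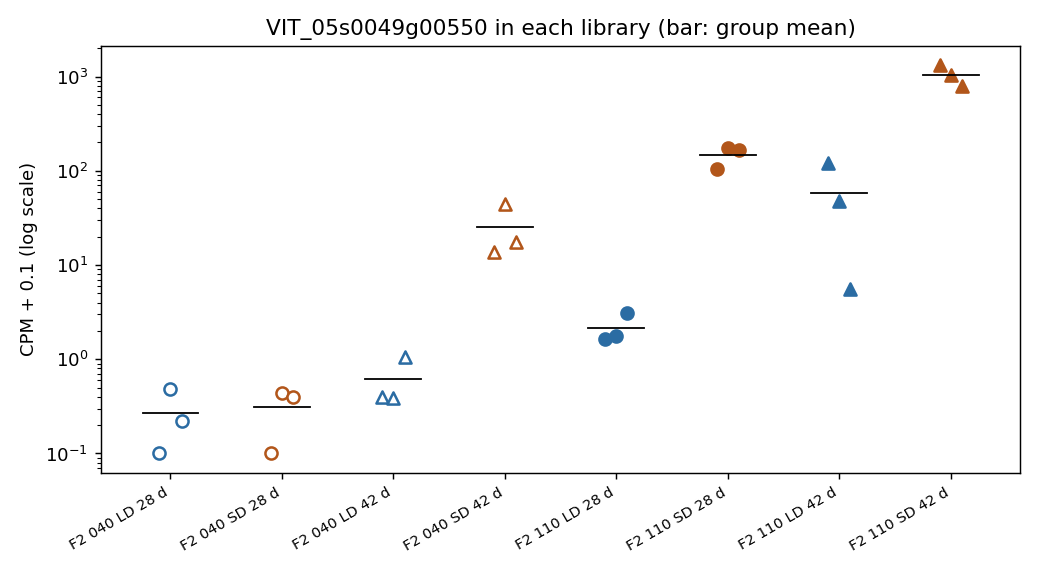
CPM + 0.1 of VIT_05s0049g00550 in the 24 libraries on a log scale (blue LD, orange SD; open F2 040, filled F2 110; circles 28 days, triangles 42 days; bars are group means). The F2 040 SD 28 d libraries lie at the level of LD, and the other 3 SD groups lie above their LD group.

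VIT_05s0049g00550 was called in 3 of the 4 comparisons of SD with LD; in F2 040 on day 28 its log2 fold change was 0.23 (edgeR Benjamini-Hochberg adjusted p = 0.962). The differences of its effect did not pass the test: they were 5.97 and -1.38 on the log2 scale between genotypes on days 28 and 42, and 5.32 and -2.03 between days in F2 040 and F2 110, with edgeR Benjamini-Hochberg adjusted p of 0.21, 0.682, 0.165 and 0.321. VIT_19s0015g00540 and VIT_00s0194g00380 were likewise called higher in SD in the same 3 comparisons. In F2 040 on day 28 their log2 fold changes were 2.56 and 2.69 (edgeR Benjamini-Hochberg adjusted p of 0.232 and 0.414). VIT_00s0194g00380 stayed under 1 CPM outside F2 110 SD 42 d. The genes called in F2 040 on day 42 and in F2 110 on day 42, which share no library, went the same way in 592 genes higher and 496 lower in SD, against 104.8 and 131.5 expected of independent lists, and opposite ways in 12 (239.6 expected). The lists came from 1 fit with a shared filter and estimate of the spread. With 1 library left out they fell to as few as 1098 genes (F2 040, without SD replicate 2) and 1041 (F2 110, without LD replicate 3). F2 040 on day 42 and F2 110 on day 28 shared 212 higher and 166 lower genes (36.4 and 34.8 expected), with 9 opposite (71.4 expected). By contrast, F2 040 on day 28 and F2 040 on day 42 shared 97 higher and 51 lower genes (125.7 and 51.6 expected), and 402 genes went opposite ways (171.5 expected). F2 040 on day 28 and F2 110 on day 42 shared 23 higher and 38 lower genes, with 439 opposite (159.3 expected). F2 040 and F2 110 shared 123 higher and 58 lower genes on day 28 (30.4 and 14.2 expected), with 34 opposite (45.4 expected). The days in F2 110 shared 152 and 91 (25.4 and 36.3 expected), with 24 opposite (61.25 expected). In at least 1 of the 4 comparisons 6857 genes were called; 6 were higher and 6 lower in SD in all 4, and 16 were called in all 4 with mixed directions.

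**Figure D3:**
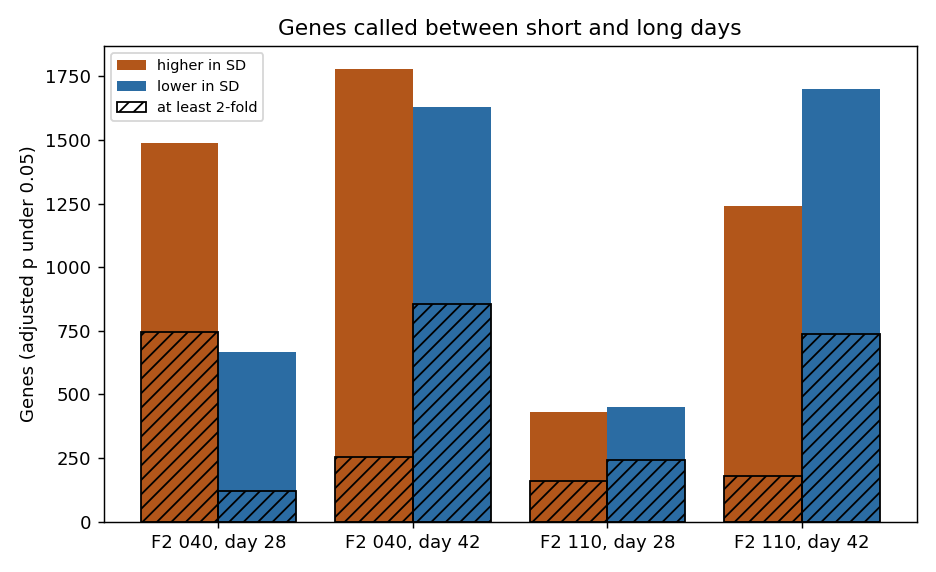
Number of genes called higher (orange) and lower (blue) in SD than in LD in each genotype on each day, with the part changed at least 2-fold hatched. The bars stand at 1488 and 667, 1781 and 1631, 431 and 450, and 1241 and 1700 genes from left to right.

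Whether the SD effect differed between the genotypes was tested on each day. On day 28 VIT_16s0098g01060 went from 69.8 ± 65.9 CPM in LD to 326 ± 136 CPM in SD in F2 110, and from 62.5 ± 35.5 to 18.3 ± 5.55 CPM in F2 040 (SD, n = 3), a difference of 4.15 ± 0.996 (SE) on the log2 scale. VIT_12s0035g00900 went from 0.583 ± 0.178 to 7.38 ± 1.22 CPM in F2 110 and from 0.438 ± 0.0718 to 0.405 ± 0.0893 CPM in F2 040 (3.90 ± 0.83). VIT_14s0128g00660 went from 6.28 ± 0.838 to 1.16 ± 0.639 CPM in F2 110 and from 0.332 ± 0.255 to 9.88 ± 6.59 CPM in F2 040 (-7.12 ± 0.98). VIT_07s0005g02310 likewise went from 1.09 ± 0.326 to 0.0986 ± 0.1001 CPM and from 0.457 ± 0.436 to 6.51 ± 3.84 CPM (-6.97 ± 0.96). Adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.038, 0.0214, 0.00125 and 0.00125. In all, 378 genes were called, 116 with a higher and 262 with a lower effect in F2 110; DESeq2 called 1088, 471 higher and 617 lower. The count was 224, 221 and 110 without F2 040 LD replicates 2 and 3 and SD replicate 2. It was 145, 178 and 799 without F2 110 LD replicates 1, 2 and 3 and 814, 124 and 113 without F2 110 SD replicates 1, 2 and 3. The calls of VIT_16s0098g01060 and VIT_12s0035g00900 ended without F2 040 LD replicate 2 or 3, F2 040 SD replicate 2, F2 110 LD replicate 1 or 2 or F2 110 SD replicate 2 or 3, and that of VIT_16s0098g01060 also without F2 040 SD replicate 1, with edgeR Benjamini-Hochberg adjusted p up to 0.117 and 0.0685. In a fit of only the 12 libraries compared it was 0.0503 for VIT_16s0098g01060 by the same edgeR test. The difference of VIT_16s0098g01060 was 3.53 without F2 040 LD replicate 3 and 5.29 without F2 110 LD replicate 3. That of VIT_14s0128g00660 was -7.90, -6.46 and -7.75 without F2 040 LD replicate 1, F2 040 SD replicate 2 and F2 110 SD replicate 3. For VIT_07s0005g02310 it was -7.99 and -8.33 without F2 040 LD replicate 1 and F2 110 SD replicate 3. With the replicate number as a block edgeR called more genes, as listed below with the other settings.

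On day 42 the difference between genotypes passed in 33 genes, 3 with a higher and 30 with a lower effect in F2 110. VIT_08s0007g04820 went from 46.7 ± 7.50 CPM in LD to 9.02 ± 1.08 CPM in SD in F2 040 and from 30.6 ± 5.87 to 22.5 ± 4.85 CPM in F2 110 (SD, n = 3; difference 1.99 ± 0.36 on the log2 scale, SE). VIT_00s0215g00040 went from 33.1 ± 1.63 to 27.0 ± 0.554 CPM in F2 040 and from 42.1 ± 1.17 to 49.6 ± 2.84 CPM in F2 110 (0.58 ± 0.09). VIT_15s0046g00720 went from 1.10 ± 0.610 to 2.63 ± 0.407 CPM in F2 040 and from 1.83 ± 0.976 to 0.459 ± 0.0552 CPM in F2 110 (-3.23 ± 0.61). VIT_02s0025g03330 went from 13.8 ± 3.62 to 17.7 ± 2.46 CPM in F2 040 and from 1.04 ± 0.444 to 0.271 ± 0.0398 CPM in F2 110 (-2.19 ± 0.41). By edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p was 0.0432, 0.0426, 0.0464 and 0.0466, and 2436 genes had an unadjusted p under 0.05. With median-of-ratios size factors edgeR called 2 genes, 1 higher and 1 lower; DESeq2 called 198. With no low-count filter and in a fit of only the 12 libraries compared edgeR called 0 genes, with 2514 and 2188 at an unadjusted p under 0.05, and by limma on log2(FPKM + 0.1) and log2(FPKM + 1) 1 and 6 genes were called. None of the 4 genes passed in any of these 4 fits, and only VIT_00s0215g00040 of them passed with median-of-ratios size factors. The edgeR count was 0 without F2 040 LD replicate 1 or 3, F2 040 SD replicate 1 or 2, or F2 110 SD replicate 1 or 2, with 1804 to 2387 genes at an unadjusted p under 0.05, and 7, 9, 2, 64 and 8 without F2 040 SD replicate 3, F2 110 LD replicates 1, 2 and 3 and F2 110 SD replicate 3. The 4 genes lost their calls in each of these cases, except that none did without F2 110 LD replicate 3 and VIT_02s0025g03330 did not without F2 110 LD replicate 1.

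Whether the SD effect differed between days was tested in each genotype. In F2 040, VIT_12s0035g00900 rose on day 42 from 0.249 ± 0.0293 CPM in LD to 3.41 ± 0.674 CPM in SD and was at 0.438 ± 0.0718 and 0.405 ± 0.0893 CPM on day 28 (SD, n = 3; difference 3.93 ± 0.88 on the log2 scale, SE). VIT_00s0187g00050 went from 3.49 ± 2.37 to 0.966 ± 0.320 CPM on day 28 and from 0.633 ± 0.151 to 2.02 ± 1.05 CPM on day 42 (3.57 ± 0.84). VIT_05s0049g00790, with 1 count over LD 28 d, went from 1.44 ± 2.04 to 0.1997 ± 0.0754 CPM on day 42, and VIT_14s0060g01780 went from 0.168 ± 0.145 to 0.613 ± 0.351 CPM on day 28 and from 5.83 ± 3.89 CPM to 1 count over the SD libraries on day 42. The Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test was 0.00593, 0.00789, 0.00382 and 0.03, and 3377 genes were called, 1584 with a higher and 1793 with a lower effect on day 42. The count was 2213 without LD 28 d replicate 2, 2202 without SD 28 d replicate 2 and 2214 without LD 42 d replicate 1. VIT_14s0060g01780 lost its call without any 1 of 8 libraries, LD 28 d replicates 2 and 3, SD 28 d replicates 2 and 3, LD 42 d replicate 1 and SD 42 d replicates 1, 2 and 3, with edgeR Benjamini-Hochberg adjusted p up to 0.078. The difference of VIT_00s0187g00050 was 2.90 without LD 28 d replicate 2.

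In F2 110, VIT_07s0031g01120 went from 2.48 ± 1.72 CPM in LD to 0.0849 ± 0.0227 CPM in SD on day 28 and from 0.358 ± 0.137 to 1.11 ± 0.902 CPM on day 42 (SD, n = 3; difference 6.43 ± 1.05 on the log2 scale, SE). VIT_13s0067g01880 went from 3.80 ± 1.15 to 0.302 ± 0.158 CPM and from 0.466 ± 0.273 to 0.551 ± 0.213 CPM (3.90 ± 0.84). VIT_19s0090g01350 went from 0.139 ± 0.0674 to 4.99 ± 1.07 CPM and from 1.04 ± 0.560 to 1.46 ± 0.404 CPM (-4.53 ± 0.86), and VIT_03s0063g01160 from 0.355 ± 0.0945 to 3.80 ± 0.424 CPM and from 1.57 ± 1.13 to 0.922 ± 0.549 CPM (-4.11 ± 0.86). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, p was 0.00369, 0.0207, 0.0104 and 0.0183. In all, 470 genes were called, 106 with a higher and 364 with a lower effect on day 42; DESeq2 called 913, 326 higher and 587 lower. A fit of only the 12 F2 110 libraries called 140 genes, with an edgeR Benjamini-Hochberg adjusted p of 0.0664 for VIT_03s0063g01160, and limma on log2(FPKM + 0.1) gave that gene 0.0649. The difference of VIT_07s0031g01120 was 5.78 without LD 28 d replicate 3 and 5.53 without SD 42 d replicate 3. The count was 224 without LD 28 d replicate 1, 174 and 242 without SD 28 d replicates 2 and 3, 200 without LD 42 d replicate 2, and 231 and 179 without SD 42 d replicates 1 and 2. By edgeR's Benjamini-Hochberg adjusted p, VIT_13s0067g01880 was at 0.0675 and 0.0564 without SD 28 d replicates 2 and 3, 0.0532 without LD 42 d replicate 2 and 0.0752 without SD 42 d replicate 2, and VIT_03s0063g01160 at 0.0545 without LD 28 d replicate 1 and 0.0538 without LD 42 d replicate 2.

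The siblings were compared directly under LD. On day 28, VIT_19s0027g01010 and VIT_19s0027g01570 stood at 34.1 ± 4.47 and 33.99 ± 6.19 CPM in F2 110 (SD, n = 3) and had no count in F2 040, at least 543-fold and 546-fold higher. VIT_02s0033g00550 was at 42.7 ± 4.36 CPM in F2 040 with no count in F2 110, at least 688-fold lower. VIT_03s0088g00710 was at 51.5 ± 85.0 CPM in F2 040, with 1 library at 150 CPM, and had 1 count in F2 110, in LD replicate 1, a ratio of 2523 with a counting interval of 452.4 to 99690, or 115.6 (20.1 to 4624) without that library, F2 040 LD replicate 1. Without the library of the 1 count its fitted log2 fold change went from -10.78 to -12.59. On day 42, VIT_19s0027g01010 and VIT_19s0027g00990 were at 35.5 ± 3.19 and 33.2 ± 6.62 CPM in F2 110 with no count in F2 040, at least 614-fold and 569-fold higher, and VIT_00s2851g00010 and VIT_00s0912g00010 were at 14.9 ± 7.93 and 13.1 ± 0.735 CPM in F2 040 with no count in F2 110, at least 202-fold and 176.5-fold lower. Adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 9.72e-11, 3.54e-09, 6.95e-10 and 0.00084 on day 28 and 8.23e-11, 6.06e-09, 6.35e-07 and 1e-10 on day 42. In all, 4013 genes were called on day 28, 2130 higher and 1883 lower in F2 110, and 4542 on day 42, 2185 higher and 2357 lower. Of these, 1926 went the same way on both days (431.3 expected of independent lists) and 103 opposite ways. In a fit of only the libraries compared, 2314 and 1785 genes were called, and VIT_03s0088g00710 had an edgeR Benjamini-Hochberg adjusted p of 0.0623.

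Day 42 was compared with day 28 within each photoperiod. Under SD in F2 040, VIT_05s0049g00550 rose from 0.212 ± 0.185 to 25.2 ± 16.8 CPM (SD, n = 3; log2 fold change 6.90 ± 1.09, SE) and VIT_19s0085g00920 from 0.669 ± 0.196 to 10.3 ± 4.01 CPM (4.004 ± 0.87). VIT_14s0068g01400 and VIT_04s0023g02310, at 2.08 ± 0.619 and 2.64 ± 3.70 CPM on day 28, had no count on day 42, at least 28.1-fold and 34.8-fold lower. The latter bound was 7.08-fold without SD 28 d replicate 3, which held 94 of its 109 counts. Under SD in F2 110, VIT_00s2419g00010 rose from 2.87 ± 1.03 to 70.7 ± 6.03 CPM (4.58 ± 0.49) and VIT_00s0908g00010 from 3 counts over the group to 2.25 ± 0.247 CPM, a ratio of 35.7 with a counting interval of 11.9 to 175.6. VIT_02s0154g00290, at 7.32 ± 4.07 CPM on day 28, had no count on day 42, at least 126-fold lower (78.1-fold without SD 28 d replicate 3), and VIT_04s0008g01500 fell from 56.9 ± 79.1 to 0.448 ± 0.107 CPM, with 1 library at 148 CPM. The Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test was 0.000607, 0.00376, 0.000645 and 0.0339 in F2 040 and 1.02e-05, 0.000577, 0.00126 and 0.0258 in F2 110. The test called 4630 genes in F2 040, 2517 higher and 2113 lower on day 42, and 5154 in F2 110, 2469 higher and 2685 lower; 2287 went the same way (563.9 expected of independent lists) and 30 opposite ways. The F2 040 count was 2562 without SD 28 d replicate 2 and 2593 without SD 42 d replicate 2, and the F2 110 count 3349 and 2833 without SD 42 d replicates 1 and 2. VIT_04s0023g02310 reached an edgeR Benjamini-Hochberg adjusted p of 0.208 without SD 28 d replicate 3 and 0.0912, 0.084 and 0.079 without SD 42 d replicates 1, 2 and 3, and VIT_04s0008g01500 reached 0.147, 0.0858, 0.0912 and 0.0682 without the same replicates in F2 110. Limma on log2(FPKM + 0.1) and log2(FPKM + 1) gave VIT_04s0023g02310 a Benjamini-Hochberg adjusted p of 0.0525 and 0.176. The log2 fold change of VIT_05s0049g00550 was 6.20 without SD 42 d replicate 2 and that of VIT_04s0008g01500 was -4.60 without SD 28 d replicate 3.

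Under LD in F2 040, VIT_13s0067g01370 and VIT_15s0046g03080 rose from 1 count each over LD 28 d, in replicates 1 and 2, to 2.69 ± 4.11 and 2.31 ± 2.57 CPM in LD 42 d (SD, n = 3), ratios of 127.3 and 109.7 with counting intervals of 22.5 to 5062 and 19.3 to 4370. Without LD 42 d replicate 1 the ratios were 15.1 (2.19 to 649.3) and 39.8 (6.59 to 1624). Without the library of the 1 count the fitted log2 fold changes went from 6.48 to 8.31 and from 6.27 to 8.12. VIT_00s0187g00090 fell from 2.83 ± 1.501 to 0.0771 ± 0.0878 CPM (log2 fold change -5.10 ± 0.99, SE) and VIT_15s0021g02700 from 38.0 ± 61.5 to 1.30 ± 0.552 CPM (-4.83 ± 1.09), with 1 library at 109 CPM. Under LD in F2 110, VIT_05s0049g00550 rose from 2.07 ± 0.815 to 58.3 ± 58.7 CPM and VIT_19s0085g00920 from 0.125 ± 0.115 to 5.13 ± 4.38 CPM. In LD 42 d replicate 3, which lay apart from replicates 1 and 2, these genes were at only 5.47 and 0.133 CPM. The latter value lies within the LD 28 d range of 0 to 0.226 CPM. Under LD in F2 110 VIT_02s0154g00280 fell from 544 ± 96.03 to 19.9 ± 25.8 CPM, and VIT_18s0001g15240 from 2.37 ± 1.73 CPM to 2 counts over the group, a ratio of 51.2 with a counting interval of 13.9 to 427.5. Both counts of VIT_18s0001g15240 were in LD 42 d replicate 3, without which none was left and the fitted log2 fold change went from -5.41 to -8.21. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, p was 0.0436, 0.00568, 0.00396 and 0.0107 in F2 040 and 0.00201, 0.00719, 0.00705 and 0.00782 in F2 110. The test called 1793 genes in F2 040, 1150 higher and 643 lower on day 42, and 2317 in F2 110, 1198 higher and 1119 lower; 385 went the same way (99.5 expected of independent lists) and 66 opposite ways. The F2 040 count was 874 and 1045 without LD 28 d replicates 2 and 3 and 562 without LD 42 d replicate 1. With the replicate number as a block over all 24 libraries it was 2875. Same-numbered libraries of this contrast varied together, but that block is not a pairing of its libraries alone. In fits of only the libraries compared, 167 genes were called in F2 040, where edgeR's Benjamini-Hochberg adjusted p was 0.0796 for VIT_15s0046g03080 and 0.174 for VIT_15s0021g02700. Such a fit called 65 genes in F2 110, and by edgeR's Benjamini-Hochberg adjustment p was 0.129 for VIT_05s0049g00550 and 0.124 for VIT_02s0154g00280. With the replicate block added to it, a fit chosen after seeing the data, 0 genes were called there. The numbers did not pair those libraries, and edgeR's Benjamini-Hochberg adjusted p was then 0.237 and 0.139 for these genes. For VIT_15s0021g02700 it was 0.201 with the block within only the F2 040 libraries compared, chosen after seeing the data, and limma on log2(FPKM + 0.1) and log2(FPKM + 1) gave 0.0792 and 0.0923. Limma on log2(FPKM + 1) gave VIT_19s0085g00920 in F2 110 a Benjamini-Hochberg adjusted p of 0.0724. The F2 110 count was 1117 and 1344 without LD 28 d replicates 1 and 2 and 908, 723 and 4766 without LD 42 d replicates 1, 2 and 3. VIT_13s0067g01370 lost its call without any 1 of LD 28 d replicates 1, 2 and 3 and LD 42 d replicate 1, and VIT_15s0021g02700 without LD 28 d replicate 1 or LD 42 d replicate 1, with edgeR Benjamini-Hochberg adjusted p up to 0.417 and 0.311. The log2 fold change of VIT_00s0187g00090 was -6.27 without LD 42 d replicate 2 and that of VIT_15s0021g02700 -0.99 without LD 28 d replicate 1. In F2 110 that of VIT_05s0049g00550 was 3.68 without LD 42 d replicate 1 and that of VIT_02s0154g00280 -6.78 without LD 42 d replicate 2.

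**Figure D4:**
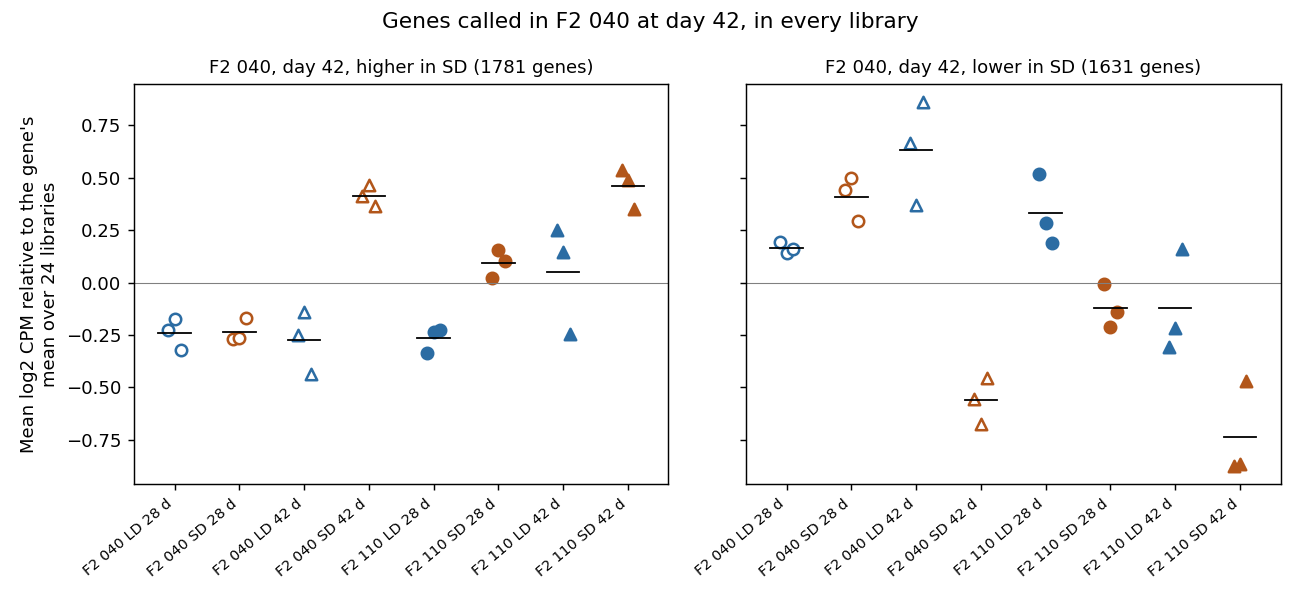
Mean log2 CPM, relative to each gene's mean over the 24 libraries, of the genes called higher and lower in SD in F2 040 on day 42, in each library (points) and as group means (bars). The lower genes averaged -0.56 in F2 040 SD 42 d and -0.74 in F2 110 SD 42 d.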

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

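The test on leaving out single libraries of F2 040 on day 28, the sorting of relabelings by kind and the tests of genes in differences they were not named for were chosen after the results were seen. The first results stand here because the SD effect differed between genotypes or between days by a test of the difference itself.

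Between genotypes on day 28, 378 genes passed the test of the difference, and none of the 24 other relabelings of the photoperiod within each genotype called as many (highest 77, 1 of 25 with the real one). The named genes were VIT_16s0098g01060 (difference of log2 effects 4.15), VIT_12s0035g00900 (3.90), VIT_14s0128g00660 (-7.12) and VIT_07s0005g02310 (-6.97). On day 42 the count was 33, and 3 of 25 relabelings, the real one included, called as many or more (highest 623). VIT_08s0007g04820 (1.99), VIT_00s0215g00040 (0.58), VIT_15s0046g00720 (-3.23) and VIT_02s0025g03330 (-2.19) were named there.

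Between days, 3377 genes differed in F2 040, against at most 762 in the other 24 relabelings (1 of 25 with the real one). The genes named by their difference of log2 effects were VIT_12s0035g00900 (3.93), VIT_00s0187g00050 (3.57), VIT_05s0049g00790 (-9.31) and VIT_14s0060g01780 (-9.20). VIT_05s0049g00790 and VIT_14s0060g01780 had 1 count over a group, so the size of their difference is not determined: the fitted value of the former was -11.16 without LD 28 d replicate 1 and -6.74 without LD 42 d replicate 3, and that of the latter -11.24 without SD 42 d replicate 2. In F2 110 the count was 470 and 2 of 25 relabelings, the real one included, reached it (highest 838). VIT_07s0031g01120 (6.43), VIT_13s0067g01880 (3.90), VIT_19s0090g01350 (-4.53) and VIT_03s0063g01160 (-4.11) were named there.

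Genes named for SD against LD differed as well where they had not been named. VIT_00s0187g00090 differed by 6.96 between days in F2 040, or 8.88, 8.11 and 4.65 without SD 28 d replicate 2, LD 42 d replicate 2 and SD 42 d replicate 3, and in the last case edgeR's Benjamini-Hochberg adjusted p was 0.103. It had been named for its fall of -4.15 on day 28, which is 1 side of this difference, so that choice favoured a large value. Its level was 2.83 CPM in LD 28 d, 0.161 in SD 28 d, 0.0771 in LD 42 d and 0.564 in SD 42 d. VIT_02s0154g00290 differed by -8.80 between days in F2 040 (-10.65 without SD 42 d replicate 3) and by -5.80 between genotypes on day 28 (-6.43 without F2 110 SD replicate 3), and these calls held with any 1 library left out. In F2 040 its SD effect was a rise on day 28 and a fall on day 42. Its level in SD 28 d, 29.5 CPM, was near that in LD 42 d, 30.3 CPM. F2 110 LD 28 d was at 29.7 CPM. The rise thus lay in the low F2 040 LD 28 d libraries, at 1.95 CPM, which enter both differences. The genes named for other comparisons passed in 12 further pairs of gene and difference. Some of these pairs share libraries with the comparison that named the gene and are not independent of that choice.

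The relabelings were of different kinds. In each of the 4 tests 19 of the 24 other relabelings mixed the photoperiods on both sides of the difference, and the highest count among these was 1, in F2 040 between days, and 0 elsewhere; mixing also widens the spread within a group. The other 5 left 1 side as labelled, and the SD effect of that side then stood against a mixed one, which is a difference of effects in itself and a structure of the samples. Every relabelling that reached the real count, 2 between genotypes on day 42 and 1 between days in F2 110, was of that kind. Neither kind stands for libraries without any SD effect, so these counts do not exclude chance for any of the 4 results.

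A signal also appeared in the FPKM table, which the comparisons by edgeR do not use. In it, 52 genes with no count in any of the 24 libraries had a mean FPKM of at least 1, and the highest such mean was 341.8. In the other direction, 47 genes with a mean CPM of at least 1 had an FPKM of 0 in every library. The cause was not tested.

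In F2 040, SD against LD called 2155 genes on day 28 and 3412 on day 42, and more of the genes called on both days went opposite ways than the same way. A candidate explanation is that the LD 28 d libraries stand apart from the other F2 040 libraries: SD 28 d against LD 42 d, a comparison without them, called 10 genes by edgeR, though 2808 of 21081 had an unadjusted p under 0.05, so the 2 groups were not shown to be alike. The log2 differences of SD 28 d and of LD 42 d from LD 28 d had a covariance of 0.203 across genes, beside 0.0522 for simulated unchanged groups that share the same libraries. Of the F2 040 day 28 calls, 123 higher and 58 lower ones were shared with F2 110 on day 28, which has no library in common (30.4 and 14.2 expected). Only 34 went opposite ways (45.4 expected), so the explanation was not shown to cover all the day 28 calls. That 1 library decided the day 28 calls was neither shown nor excluded, since the lowest count with 1 of the 6 left out was 966, without SD 28 d replicate 2. If LD 28 d does stand apart, the reason, such as stage of growth, harvest or library batch, cannot be read from the labels and was not tested. The differences of the SD effect between days in F2 040 and between genotypes on day 28 use the same LD 28 d libraries. The counts of both thus depend on whether LD 28 d stands apart.

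Replicate 3 of F2 110 LD 42 d lay apart from replicates 1 and 2 and correlated with them at a mean r of 0.955 across genes, beside 0.962 with LD 28 d and 0.963 with SD 28 d. RNA of the other genotype was argued against, since 17 genes counted in F2 040 and hardly in F2 110, a choice made without the F2 110 LD 42 d libraries, summed there to 0.242% of their F2 040 level. Unequal depth was argued against as well, since after thinning to the same total replicate 3 was still 3.29 times as far from the others as these were from each other. Labels exchanged with an F2 110 LD 28 d library need a partner out of place, and 0 of the 3 such libraries correlated better with LD 42 d replicates 1 and 2 than with their own group. A single wrong label or a swap with another sample stays open, and no biological explanation was tested.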

How the results depend on the processing

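The fit with the replicate block within only the libraries of a contrast was chosen after seeing the data. Counts of called genes that moved by more than 1.5 times were as follows, and the cause was not tested. Abbreviated names are SD against LD by genotype and day, "genotype difference" and "day difference" for differences of the SD effect, "siblings" for F2 110 against F2 040 under LD, and "days" for day 42 against day 28. A fit of only a contrast's libraries has fewer samples to estimate the spread. F2 110 day 28 and days SD in both genotypes lost as many samples and did not move this far. The full fit takes 1 spread per gene over all groups. Replicate pairs varied from 5.34 (F2 110 SD 42 d) to 85.8 times counting noise (F2 040 LD 42 d). Whether this unequal spread moved the counts was not tested. With only the libraries of a contrast edgeR called 1118 (F2 040 day 28), 1712 (F2 040 day 42) and 549 (F2 110 day 42). It called 0 (genotype difference day 42), 140 (day difference F2 110), and 2314 and 1785 (siblings day 28 and 42). In the same setting it called 167 (days LD F2 040) and 65 (days LD F2 110). With the replicate block over all 24 libraries it called 1492 (F2 110 day 28), 837 and 129 (genotype difference day 28 and 42), 872 (day difference F2 110) and 2875 (days LD F2 040). With the block within only the contrast's libraries it called 0 (F2 040 day 28), 1576 (F2 110 day 42), 1436 and 1 (genotype difference day 28 and 42), 212 (day difference F2 110), 2144 and 992 (siblings day 28 and 42), 2917 (days SD F2 040) and 0 (days LD F2 110). By the rule for pairing, the numbers pair the libraries in 3 contrasts only, and elsewhere the block is a shared number. Same-numbered libraries of some groups within the differences of effects varied together as well. DESeq2 called 1646 (F2 110 day 28), 1088 and 198 (genotype difference day 28 and 42) and 913 (day difference F2 110). The genotype difference on day 42 also gave 2 with median-of-ratios factors, 0 with no filter, and 1 and 6 by limma on log2(FPKM + 0.1) and log2(FPKM + 1). Where edgeR called 0, genes at an unadjusted p under 0.05 numbered 2188 and 2514 (genotype difference day 42, only its libraries and no filter), 4884 (F2 040 day 28) and 3361 (days LD F2 110); for the last of these DESeq2 called 2991 and for F2 040 day 28 2796. With 1 library left out, which kept only the siblings within 1.5 times, the counts ranged over 966 to 1953 and 1098 to 4046 (F2 040 day 28 and 42), 69 to 1004 and 1041 to 3881 (F2 110), 110 to 814 and 0 to 64 (genotype difference), 2202 to 3391 and 174 to 624 (day difference F2 040 and F2 110), 3000 to 3841 and 3231 to 5625 (siblings), 562 to 2008 and 2562 to 3735 (days LD and SD, F2 040), and 723 to 4766 and 2833 to 4712 (days LD and SD, F2 110). No named gene reversed its direction. Over all genes, calls with opposite directions in the limma fits and in edgeR numbered 1 (F2 040 day 42), 4 and 2 (siblings day 28 and 42) and 1 (days SD F2 110) with either pseudocount. For the 56 pairs of named gene and contrast, 416 of 465 values under other settings kept the call and 49 lost it, and with 1 library left out 322 of 432 kept it and 110 lost it. The block within only the contrast's libraries ended, by edgeR Benjamini-Hochberg adjusted p, the calls of VIT_00s0187g00090 (0.0504, F2 040 day 28), VIT_03s0063g01160 (0.074, day difference F2 110), VIT_05s0049g00550 and VIT_02s0154g00280 (0.237 and 0.139, days LD F2 110), and VIT_00s0215g00040, VIT_15s0046g00720 and VIT_02s0025g03330 (0.113, 0.153 and 0.134, genotype difference day 42). Alternatives for the 28 gene lists were not run, since the lists had 0 members.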

Other observations

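The tests of the score, of the genes counted in one genotype only and of the shared changes, and the excess of called pairs, were chosen after the results were seen. The 2 genotypes differed in genes that were counted in every library of one and hardly in the other. At a CPM of at least 1 in all 12 libraries of one genotype and at most 3 counts over the 12 of the other, 43 genes were found in F2 110 and 13 in F2 040; 26 and 4 of these had no count at all in the other genotype. Their median level was 5.04 CPM in F2 110 and 4.86 CPM in F2 040, and the median ratio to a level of 3 counts over 12 libraries was 307 and 299. Of the 43 genes, 16 had another of the 43 within 50 identifier numbers under the same prefix, against a mean of 0.607 and a highest value of 6 in 1000 random sets. Of the 13 genes, 0 did (random mean 0.044). In the FPKM table, 3 of the 43 and 2 of the 13 were listed at a mean of at least 1 in the genotype without counts.

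The genes called in F2 040 on day 42 were followed in the libraries outside that comparison, which had shared its filter and its estimate of the spread; with only its 6 libraries 1712 genes were called in place of 3412. A score was the mean log2 CPM of the 1781 genes higher in SD minus that of the 1631 genes lower in SD, each relative to its mean over the 24 libraries. In F2 110 it was -0.60 ± 0.23 under LD on day 28 and 0.21 ± 0.17 under SD (SD, n = 3), and 0.17 ± 0.51 under LD on day 42 and 1.196 ± 0.33 under SD. Both SD groups lay above their LD group in every library (two-sided exact permutation p = 0.1, the smallest 3 against 3 can give; 0.125 after adjustment over 5 comparisons). Under LD in F2 110 the score was higher on day 42 than on day 28 with the same p. Replicate 3 of F2 110 LD 42 d was at -0.41, beside -0.85 to -0.41 in the LD 28 d libraries, and replicates 1 and 2 were at 0.56 and 0.36. In F2 040 the score on day 28 was -0.41 ± 0.09 under LD and -0.64 ± 0.16 under SD (exact p = 0.2).

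The change under LD in F2 110 from day 28 to day 42 was compared with the SD effect in F2 040 on day 42, which shares no library with it. Of the genes called in both, 672 went the same way and 40 opposite ways, against 188 and 187 expected of independent lists, and the fold changes correlated across genes at r = 0.40. The change under LD in F2 040 was set against the SD effect in F2 110 on day 28, again without a shared library. It correlated at r = 0.066 only, with 155 genes the same way and 22 opposite ways (37.2 and 37.7 expected). Since this SD effect was that of day 28 and not of day 42, the correlations do not compare the genotypes. Genes are not independent replicates. The 2317 calls of the LD contrast in F2 110 became 1117 and 1344 without LD 28 d replicates 1 and 2 and 908, 723 and 4766 without LD 42 d replicates 1, 2 and 3. With the replicate block within only its libraries, a fit chosen after seeing the data, 0 genes were called. With 1 library left out, the lists of the second comparison fell to as few as 562 (LD, F2 040) and 69 genes (SD against LD, F2 110 on day 28).

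Genes called between the genotypes under LD on day 28 lay near one another in the identifier order within a prefix. Called pairs 11 to 50 tested genes apart numbered 24411, above the highest of 1000 shuffles (23477) and 1.09 times their mean. The shuffles moved single calls over all tested genes and so broke up immediate neighbours too. Their range is then too narrow to decide whether immediate neighbours alone account for these pairs. Tandem copies spread over 11 or more tested genes would give such pairs as well and are not excluded. On day 42 the 29726 such pairs lay within the shuffles (highest 29953, ratio 1.04), and in 3 of the 4 comparisons of SD with LD the pairs exceeded their highest shuffle as well, with 7166 pairs over 6878 and 17212 over 17208 in F2 040 on days 28 and 42 and 13667 over 12581 in F2 110 on day 42, but not the 1197 in F2 110 on day 28 (highest 1250), so such clustering is not particular to genotype. Whether chromosome segments that differ between the siblings account for the excess stays open: the ratio was as high as 1.14 in SD against LD, but it is not comparable between contrasts with different shares of called genes, and the excess over the shuffle mean was 2036 and 1064 pairs between the genotypes on days 28 and 42, beside 118 to 1650 in SD against LD. Of the called pairs 55.8% went the same way on day 28 (highest shuffle 51.2%) and 54.3% on day 42 (51.1%), whereas the 4 comparisons of SD with LD lay within their shuffles. This is consistent with reads of one haplotype failing to align over whole segments, which itself needs segments that differ, and expression shared by neighbours in such segments may give the same result.

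Other splits of the libraries were counted for the comparisons of 2 groups. Each has 10 splits, too few for a share under 0.05, and in each 1 split, the real one, reached the real count. For SD against LD the real counts and the highest of the other splits were 2155 and 1 (F2 040, day 28), 3412 and 0 (F2 040, day 42), 881 and 0 (F2 110, day 28), and 2941 and 6 (F2 110, day 42). For genotype under LD they were 4013 and 0 on day 28 and 4542 and 381 on day 42. For day 42 against day 28 they were 1793 and 185 (LD, F2 040), 4630 and 0 (SD, F2 040), 2317 and 1147 (LD, F2 110), and 5154 and 0 (SD, F2 110). The split with 1147 exchanged replicate 1 of F2 110 LD 28 d with replicate 3 of F2 110 LD 42 d.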
